A study of Homo sapiens with 24 samples.

How the data were processed

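RNA sequencing libraries were made from N/TERT-1 cells (written nTERT-1 in the labels), an immortalised human keratinocyte line, in 4 genotypes (NT, KAT2A_KD, KAT2B_KD and KAT2AB_KD) at 3 culture stages (Subconfluent, Confluent and Differentiated), with 2 libraries in each of the 12 groups. Per the labels, polyadenylated RNA was selected from total RNA, libraries were made with a directional kit, and single-end reads were sequenced. The labels do not say what NT stands for, by which method the knockdowns were made, or whether the libraries of a group come from separate cultures. The p-values measure only the spread between the libraries of a group, which may be technical.

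The deposited raw table gives read counts per gene. Per the labels, the authors used FastQC, Bowtie2, featureCounts and DESeq2 with the genome build hg19, and no version, order, annotation, strand setting or treatment of multi-mapping reads is given. A deposited table of signal values, named as DESeq2 normalized, equals the counts divided by 1 size factor per library, with a largest relative deviation of 5e-07. It was used only to check the size factors and to restore gene symbols that a spreadsheet had turned into dates in the raw table. Of 28 such symbols 26 were restored. Other deposited labels, in a sample table, give each library's genotype, stage and a replicate number of 2 or 3, here called replicate 1 and replicate 2, and put the Differentiated stage at day 4. By the rule set for this, the replicate numbers were not taken to pair the libraries, so the fits carry no replicate term. The difference between the replicates correlated between groups with a median of 0.12, over 0.1 in 37 of 66 pairs of groups. A weak effect shared by replicate number is therefore not excluded. The count table held 1 column that matched no sample, and it was not used here. No genome coordinates are given, since the available reference annotation is of another build.

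The table had 26364 genes, of which 21173 had at least 1 read. Library totals ran from 8010178 to 16054003 counts. Among genes with a total of at least 240 counts, 230 had counts in all 24 libraries that equalled another gene's (117 genes) or stood in whole multiples of 2 or more (174 genes), as when a read is counted at several near-identical genes. They hold 2.6% of all counts. Genes of this kind, genes that overlap, and antisense partners such as VIM and VIM-AS1 have uncertain counts, since neither the treatment of multi-mapping reads nor the strand setting is given.

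Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low genes were removed with filterByExpr by group, which left 15757 genes, and libraries were scaled with TMM factors. One quasi-likelihood fit (glmQLFit, glmQLFTest) covered all 24 libraries with 12 groups and no covariate, so that all groups share the estimate of the spread, with 12 residual degrees of freedom, a median prior of 7.36 degrees of freedom and a common biological coefficient of variation of 0.218. Values are in CPM, the counts of a gene scaled by library size with TMM factors, given as mean ± SD over 2 libraries. Log2 fold changes and their standard errors (SE) come from the fit, and p-values were adjusted over all genes tested by the method of Benjamini and Hochberg within each of 24 comparisons. A gene passed at an adjusted p under 0.05. The comparisons were the stage changes in NT, each knockdown against NT at each stage, KAT2A_KD against KAT2B_KD, KAT2AB_KD against each single knockdown, and the difference between each knockdown and NT in the change from Subconfluent to Differentiated. Where all libraries of a group had 0 reads, the fold is a lower bound against a floor of 3 counts over the group, and no fitted fold is given. Where a group had 1 to 3 counts, the ratio is given with its 95% counting interval. Floors and intervals cover counting error only.

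The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 6 highest and 6 lowest log2 fold changes among genes that passed, with a mean log2 CPM of at least 1 and both libraries of one group above both of the other (a condition dropped for the differences between stage changes), up to 4 members of each gene list with the lowest p, any other list member whose value and outcome are stated, and KAT2A and KAT2B always.

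The 21 gene lists were basal keratinocyte and adhesion, spinous (early) differentiation, granular and cornified envelope, SPRR and LCE families, epidermal lipid barrier, keratinocyte differentiation transcription factors, DNA replication (S phase), mitosis (G2/M), p53 targets and CDK inhibitors, SAGA and ATAC complexes without KAT2A and KAT2B, other lysine acetyltransferases, lysine deacetylases, MYC targets and ribosome biogenesis, interferon response, barrier stress and inflammation, mesenchymal and TGF-beta response, cholesterol synthesis, amino acid stress (ATF4) response, hypoxia and glycolysis, markers of fibroblasts, and markers of melanocytes. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, first with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The number of members that passed is given over all genes tested and adjusted over the list alone. Medians of lists with members at 0 reads in a group are also given with those members at their bound, where that moves the median by over 0.05 log2.

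Alternatives were DESeq2 1.42.0 (Wald test), RLE scaling in edgeR, no filter on low counts beyond 1 read in any library, a fit with the replicate number as a block, and leaving out each library of the compared groups in turn, in which case the lone library of a group is assumed to vary like the others. A fit without the genes that share reads was chosen after seeing the data. All knockdowns of a stage are compared with the same NT libraries. Overlaps of calls and correlations of fold changes are therefore given beside 20 simulations of unchanged groups. In each, all libraries, NT included, were drawn gene by gene, with the NT mean of the stage in every group. A departure shared by many genes in the real NT libraries is therefore not simulated. The pipeline was tested on simulated data for KAT2A_KD against NT at Subconfluent, with 15605 genes, 100 of them changed 2-fold and 100 changed 4-fold. It recovered 26% of the genes changed 2-fold and 75% of those changed 4-fold, with 5 false calls among 106. A shifted list gave a camera p of 9.79e-31 with the preset correlation, and 0 of 20 random lists passed. The simulated genes vary independently, so this does not test for false calls of lists whose members vary together.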

Results

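Gene expression was measured by RNA sequencing in N/TERT-1 keratinocytes of 4 genotypes, the control genotype labelled NT and knockdowns labelled KAT2A_KD, KAT2B_KD and KAT2AB_KD, at 3 culture stages. The Subconfluent and Confluent stages precede differentiation, and the Differentiated stage is day 4 in the deposited sample table. Each of the 12 groups had 2 libraries, with 8010178 to 16054003 counts per library. Between the libraries of a group, Pearson's r of log CPM across genes was 0.963 to 0.981 (genes are not independent replicates). Reads of KRT6A and its near-identical copy KRT6C stood at a ratio of 0.881 to 0.941 in every library, and both genes are uncertain. Unless a library is named beside a gene or a count, the gene passed the test and the count moved by at most 1.5 times when any 1 of the compared libraries was left out. Counts of 1 list member and counts adjusted over the list alone were not followed in this way. No list that passed a test differed in sign between its median, its mean and the test.

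KAT2A and KAT2B encode paralogous lysine acetyltransferases that occupy the same position in the SAGA and ATAC coactivator complexes. KAT2A stood at 30.1 and 32.7 CPM in the NT libraries at Subconfluent and at 3.46 and 4.12 in KAT2A_KD. At Confluent it was 37.4 ± 1.48 CPM (SD, n = 2) in NT and 4.53 ± 0.744 in KAT2A_KD, and at Differentiated 11.4 ± 1.98 in NT and 3.98 ± 1.35 in KAT2A_KD. KAT2B stood at 4.76 and 5.58 CPM in Subconfluent NT cells and at 0.152 and 1.04 in KAT2B_KD. At Confluent KAT2B was at 4.32 and 4.06 CPM in NT and 0.668 and 1.25 in KAT2B_KD, and at Differentiated at 44.8 and 40.4 against 4.58 and 8.59. In KAT2AB_KD, KAT2A was at 8.29 and 10.4 CPM, 7.35 and 1.67, and 1.98 and 6.85 over the 3 stages, and KAT2B at 1.92 and 1.19, 2.96 and 0.902, and 5.85 and 18.9. Each target gene was therefore below both NT libraries of its stage in every library labelled as its knockdown.

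**Figure D1:**
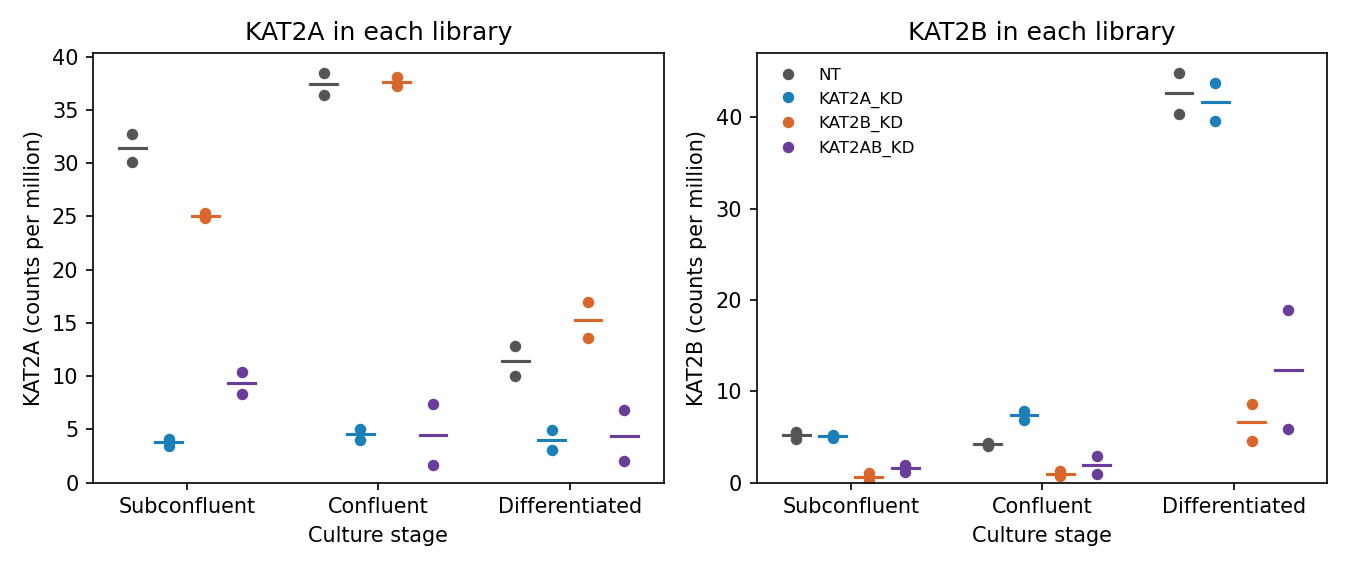
KAT2A and KAT2B in CPM (vertical axes) by culture stage (horizontal axes) in the 4 genotypes; points are libraries and short lines are means of 2. KAT2A in KAT2A_KD lies between 3.03 and 5.06 CPM, and KAT2B in NT is at 44.8 and 40.4 CPM at Differentiated.

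In the fit, KAT2A fell by 3.05 log2 in KAT2A_KD at Subconfluent (adjusted p = 0.00518, edgeR) and by 3.05 at Confluent (adjusted p = 0.00245), with -1.52 and adjusted p = 0.139 at Differentiated. The first call was lost without KAT2A_KD Subconfluent 1 (adjusted p = 0.146) or 2 (0.0727), and the second without KAT2A_KD Confluent 1 (0.0808). KAT2B fell by 2.68 log2 (SE 0.497, adjusted p = 0.00332) in KAT2B_KD at Differentiated, a call lost without KAT2B_KD Differentiated 1 (adjusted p = 0.0580). At the lower KAT2B levels of the Subconfluent and Confluent stages its changes of -3.03 (adjusted p = 0.0689) and -2.15 (adjusted p = 0.220) did not pass. In KAT2AB_KD, KAT2A fell by 1.75 (adjusted p = 0.0376), by 3.02 (0.000704), and had -1.36 (0.144) at Differentiated, and KAT2B had -1.73 (0.117) and -1.07 (0.420) before it fell by 1.78 (0.0484) at Differentiated. The Subconfluent KAT2A call in KAT2AB_KD was lost without KAT2AB_KD 1 (adjusted p = 0.310), KAT2AB_KD 2 (0.173), NT 1 (0.108) or NT 2 (0.168), and the Differentiated KAT2B call without KAT2AB_KD 1 (0.287), NT 1 (0.201) or NT 2 (0.195). No change of one paralog in the knockdown of the other passed at any stage. The largest was KAT2B in KAT2A_KD at Confluent, at 6.89 and 7.85 CPM (log2 0.81, adjusted p = 0.757).

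From Subconfluent to Confluent, interferon genes and some differentiation genes rose in NT cells. Of the 32 interferon response genes 21 rose and 0 fell, among them the antiviral GTPase MX1, at 352 ± 2.22 CPM against 44.6 ± 18.9 (log2 2.98, SE 0.41, adjusted p = 0.000630), and IFIT1, which binds foreign RNA caps, at 73.2 ± 8.19 against 10.3 ± 2.97. Of 20 spinous genes 5 rose, led by TGM1, the transglutaminase that crosslinks the cornified envelope, which was 10.1-fold higher (log2 3.33, SE 0.37, adjusted p = 0.000113), and by NOTCH3 (log2 3.04). The differentiation transcription factors GRHL3 (log2 2.43) and OVOL1 (2.44), the chemokine CXCL14 (4.53) and the glycerol channel AQP3 (3.33) also rose. The TGF-beta feedback gene PMEPA1 fell by 1.74 log2, and of 24 mesenchymal and TGF-beta genes 3 fell.

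Adjusted over the list alone, 32 interferon, 9 spinous, 8 transcription factor and 9 barrier stress genes were higher and 13 mesenchymal genes lower (2 higher). The list medians were 1.90 log2 for interferon (adjusted p = 7.47e-43, camera with the preset correlation, and 0.00697 with an estimated correlation), 0.82 for spinous (5.09e-11 and 0.00697), 0.70 for the transcription factors (1.77e-07 and 0.00697, 0.56 with members at their bound), 0.99 for barrier stress (3.82e-11 and 0.0212) and -0.77 for mesenchymal genes (5.84e-07 and 0.0150). The granular list passed with the preset correlation alone (adjusted p = 0.240 with an estimated correlation, median 0.82, or 0.36 at the bound). The same held for SPRR and LCE (0.256, 1.26, or 0.28 at the bound), lipid barrier (0.240, 0.23, or 0.0046 at the bound), hypoxia (0.394) and cholesterol genes (0.372). In all 108 genes were higher and 34 lower, a total of 142. It was 40 without NT Subconfluent 1, 49 without NT Subconfluent 2, 91 without NT Confluent 1 and 47 without NT Confluent 2. In the same order 6, 7, 16 and 9 interferon, 3, 3, 4 and 3 spinous, 1, 2, 5 and 1 barrier stress and 1, 2, 2 and 0 mesenchymal genes passed.

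Differentiation of NT cells reshaped the transcriptome, with 3833 genes higher and 4116 lower than at Confluent. All 20 spinous and all 22 measured granular genes rose, as did 25 of 25 SPRR and LCE genes, 22 of 23 lipid barrier genes and 18 of 21 differentiation transcription factors. The keratohyalin gene RPTN, at 0 reads in Confluent cells, was at least 7801-fold higher. The desmosomal cadherin DSC1 reached 3089 ± 102.8 CPM from 0.702 ± 0.215, and FLG, the precursor of filaggrin, rose by 11.68 log2 (SE 1.02, adjusted p = 1.55e-08). IVL, a cornified envelope precursor, rose 137-fold (log2 7.09, SE 0.40, adjusted p = 4.53e-11), and the homeodomain gene HOPX by 10.57 log2. KAT2B rose 10.2-fold (log2 3.34, SE 0.515, adjusted p = 2.15e-05), while KAT2A fell by 1.71 log2 (SE 0.443, adjusted p = 0.00318).

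Proliferation genes fell over the same interval, and interferon genes fell from a Confluent level that stood apart. All 28 mitosis genes were lower, with CDC20, an activator of the anaphase-promoting complex, at 1.71 ± 0.682 CPM against 204 ± 14.1, together with 27 of 28 DNA replication and 26 of 28 MYC target genes. Of the interferon genes 26 fell and 1 rose, with IFIT3 at -5.37 log2. The list level (mean log2 CPM over members) was 5.39 and 5.74 in the NT Confluent libraries, above each of the other 22, of which the highest was 4.75. From Subconfluent to Differentiated the list did not pass in NT (median -0.42, adjusted p = 0.554). Of the amino acid stress genes 17 rose and 1 fell, including ATF4 (1.79) and NUPR1 (at least 219.7-fold). VIM, the mesenchymal intermediate filament gene, fell by 4.75 log2.

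The lists that passed with both correlations were spinous (median 4.97, adjusted p = 0.00124 with an estimated correlation), granular (7.87, 0.000545), SPRR and LCE (6.70, or 6.35 at the bound, 0.0187), lipid barrier (5.02, 0.000532), transcription factors (3.34, 0.00177), replication (-3.77, 0.00980), mitosis (-5.51, 0.00980) and MYC targets (-1.94, 0.0187). With an estimated correlation the calls were lost for interferon (adjusted p = 0.157), amino acid stress (0.135), hypoxia (0.419), barrier stress (0.422, and 0.0539 with RLE scaling and the preset correlation) and the SAGA and ATAC subunits (0.0890), of which 11 fell and 1 rose of 29. No list shift passed for p53 targets (adjusted p = 0.305), other acetyltransferases (0.540), deacetylases (0.729), basal genes (0.754), mesenchymal genes (0.217), cholesterol synthesis (0.342, median -0.04, mean and test above 0), fibroblast markers (0.245) or melanocyte markers (0.570). Against Subconfluent cells, 3774 genes were higher and 4173 lower at Differentiated.

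At Subconfluent, KAT2A_KD cells had higher spinous, granular and SPRR and LCE lists and lower interferon genes than NT cells. The Notch receptor NOTCH3 was 6.65-fold higher (log2 2.73, SE 0.42, adjusted p = 0.00476), the cornified envelope gene LCE3D, at 0 reads in NT, at least 11.5-fold higher (adjusted p = 0.00518), TGM1 2.30 log2 higher (adjusted p = 0.00547) and the matrix metalloprotease MMP10 1.65 higher (adjusted p = 0.00476). VIM fell by 1.74 (adjusted p = 0.00718) and MX1 by 2.22 (adjusted p = 0.0206). The microfibril gene MFAP5, which the rule names by its size, fell to 18.2 ± 1.09 CPM from 68.7 ± 7.26 (log2 -1.92, SE 0.20, adjusted p = 0.000178). Among these genes MFAP5 alone passed without each library in turn. The NOTCH3 call was lost without NT 1 (adjusted p = 0.0865) or NT 2 (0.0767), LCE3D without NT 1 (0.0912) or NT 2 (0.0687), and MMP10 without KAT2A_KD 1 (0.0829) or NT 2 (0.0975). Likewise TGM1 was lost without KAT2A_KD 1 (0.0760), NT 1 (0.0579) or NT 2 (0.126), VIM without KAT2A_KD 1 (0.221), KAT2A_KD 2 (0.0727) or NT 2 (0.157), and MX1 without KAT2A_KD 1 (0.303), KAT2A_KD 2 (0.195) or NT 1 (0.289).

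As groups, 3 of 20 spinous, 1 of 22 granular and 3 of 25 SPRR and LCE genes rose at Subconfluent and 2 of 32 interferon genes fell. Adjusted over the list alone these were 6, 7, 12 and 19. The medians were 0.73 (adjusted p = 0.0184 with an estimated correlation), 0.66 (0.0216), 1.61 (0.0216, or 1.5 at the bound, and a fitted 3.95 without NT 1) and -1.10 (0.0216). That of the p53 targets, with 0 members past the threshold, was -0.28 (0.0242). Lists that passed with the preset correlation alone were the transcription factors (adjusted p = 0.154 with an estimated correlation), lipid barrier (0.191, median 0.22 but -0.05 at the bound), amino acid stress (0.191), barrier stress (0.217) and mitosis (0.587). In total 42 genes were higher and 12 lower, 54 in all. The total was 12 without KAT2A_KD 1, 18 without KAT2A_KD 2, 15 without NT 1 and 11 without NT 2, and in that order 1, 2, 0 and 0 spinous, 2, 1, 0 and 0 SPRR and LCE, 0, 0, 0 and 1 interferon and 0 granular genes passed.

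At Confluent, where the NT libraries had the highest interferon levels of all 24, 24 of 32 interferon genes were lower and 0 higher in KAT2A_KD. MX2 fell by 4.40 log2 (SE 0.49, adjusted p = 8.29e-05), from 93.4 ± 12.6 CPM in NT to 4.48 ± 1.58, and MX1 by 3.78 (SE 0.43), from 352 ± 2.22 to 25.7 ± 2.53. The stromelysins MMP10 (log2 3.11, SE 0.27, adjusted p = 6.80e-06) and MMP3 (3.97, SE 0.51) and the actin-bundling gene LCP1 (3.54) rose. The differentiation factor MAF rose by 1.88 log2 (adjusted p = 0.00192, but 0.0544 without NT 1). Of the spinous genes 1 rose, and 0 granular and 0 SPRR and LCE genes passed.

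The interferon list had a median of -2.39 (adjusted p = 7.76e-70, and 0.00125 with an estimated correlation), with 32 members lower when adjusted over the list alone. Calls lost with an estimated correlation were spinous (adjusted p = 0.0675, median 0.63, 8 higher adjusted over the list alone), granular (0.122, 0.77, or 0.70 at the bound), SPRR and LCE (0.102, 1.38, or 1.35 at the bound, 6 higher over the list alone), transcription factors (0.102), mesenchymal genes (0.122, 4 rose, 1 fell), other acetyltransferases (0.568) and mitosis (0.575). There were 42 genes higher and 60 lower (with DESeq2 52.9% of 187 were higher). Their sum came to 57 without KAT2A_KD 1, 36 without KAT2A_KD 2, 35 without NT 1 and 37 without NT 2, with 16, 13, 18 and 16 interferon, 2, 3, 1 and 2 risen mesenchymal and 0 spinous genes.

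In differentiated cultures the interferon genes of KAT2A_KD stood on the other side, above NT. Of 32 genes 16 rose and 0 fell. IFIT3 was 11.6-fold higher (log2 3.54, SE 0.38, adjusted p = 4.70e-05, 22.7 ± 10.7 CPM against 1.93 ± 0.734) and IFIT1 3.11 log2 higher (SE 0.40, adjusted p = 0.000538). The metalloproteases MMP10 (log2 2.86, SE 0.25, adjusted p = 7.46e-06) and MMP1 (2.42, SE 0.25) rose as well. Of 28 mitosis genes 3 rose, including the spindle gene TPX2 (log2 1.45, adjusted p = 0.00670, lost without KAT2A_KD 2 at 0.0908 or NT 2 at 0.149). No granular, SPRR and LCE or lipid barrier gene passed in either direction.

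List medians that passed with both correlations were 1.32 for interferon (adjusted p = 0.0393 with an estimated correlation, 23 members adjusted over the list alone), 1.13 for mitosis (0.0393, 12), 0.70 for mesenchymal and TGF-beta genes (0.0279, 9, of which 4 rose over all genes), -0.63 for amino acid stress (0.0393, 10) and -0.45 for the lipid barrier (0.0393). With an estimated correlation the calls were lost for granular (adjusted p = 0.142, median -0.36), replication (0.157), cholesterol (0.146), hypoxia (0.142) and barrier stress genes (0.221). In total 145 genes were higher and 47 lower, 192 in all, against 49 without KAT2A_KD 1, 99 without KAT2A_KD 2, 75 without NT 1 and 17 without NT 2. The interferon genes that passed were then 2, 10, 5 and 2, the mitosis genes 1, 1, 3 and 0, and the mesenchymal genes 2, 3, 3 and 2.

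Before differentiation, KAT2B_KD cells had lower interferon genes than NT cells and, at Subconfluent, higher amino acid stress genes, and no differentiation list passed upward. At Subconfluent 5 of 32 interferon genes fell, including MX1 (log2 -3.24, SE 0.45, adjusted p = 0.00368, 4.71 ± 0.736 CPM against 44.6 ± 18.9), IFIT1 (-2.70, adjusted p = 0.0102) and IFI44 (-2.80, adjusted p = 0.0102). The secreted stress glycoprotein STC2 rose by 3.18 log2 (SE 0.61, adjusted p = 0.0474) and the AP-1 partner JDP2 by 1.72 (adjusted p = 0.0215), and GRHL3 fell by 1.96 (adjusted p = 0.0202). Each of these calls was lost in some fits with 1 library left out. In the order without KAT2B_KD 1, KAT2B_KD 2 and NT 1, the adjusted p was 0.141, 0.0994 and 0.0512 for MX1, 0.240, 0.202 and 0.134 for IFIT1, 0.141, 0.243 and 0.0894 for IFI44, and 0.367, 0.0994 and 0.273 for GRHL3. For STC2 it was 0.141, 0.367, 0.342 and, without NT 2, 0.340, and for JDP2 0.141, 0.243, 0.273 and 0.193.

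The interferon list had a median of -1.59 (adjusted p = 1.64e-49, and 0.00544 with an estimated correlation, 28 lower adjusted over the list alone) and the amino acid stress list 0.80 (8.49e-20 and 0.00544, 0.61 at the bound). Of the latter 1 rose, 0 without any 1 library, and 10 adjusted over the list alone. The p53 list had -0.31 (0.000302 and 0.0244) with 0 members past the threshold and 1 adjusted over the list alone, and the granular list -0.33 (adjusted p = 0.457 with an estimated correlation). In all 3 genes were higher and 11 lower, 14 together, against 2 without KAT2B_KD 1, 0 without KAT2B_KD 2 by the same edgeR test, 1 without NT 1 and 8 without NT 2, with 0, 0, 0 and 4 interferon genes. At an unadjusted p under 0.05 there were 705 genes, no more than 15757 tests give on average with no change, and DESeq2 called 66.

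At Confluent, 28 of 32 interferon genes fell in KAT2B_KD. MX2 fell by 4.63 log2 (SE 0.50, adjusted p = 2.73e-05). MX1 went from 352 ± 2.22 to 17.3 ± 2.18 CPM (log2 -4.35, SE 0.45), and the RNA sensor gene DDX58 also fell (-3.41). MAF was 6.91-fold higher (log2 2.79, SE 0.28, adjusted p = 1.58e-05). The antimicrobial gene S100A7 was at least 32.1-fold lower (adjusted p = 0.00271, but 0.0984 without KAT2B_KD 1), and the elastase inhibitor PI3 fell by 2.73 (adjusted p = 0.0239, but 0.415 without KAT2B_KD 1 and 0.413 without NT 2).

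The interferon median was -2.93 (adjusted p = 2.81e-86, and 0.000452 with an estimated correlation), with 32 members lower adjusted over the list alone. Calls lost with an estimated correlation were barrier stress (adjusted p = 0.166, median -0.90, or -0.83 at the bound, 10 lower adjusted over the list alone), granular (0.356, -0.69, or -0.13 at the bound), basal (0.356, 0.33), MYC targets (0.483), mesenchymal genes (0.304), other acetyltransferases (0.654) and amino acid stress (0.635). Of the 73 changed genes 11 were higher and 62 lower. There were 20 without KAT2B_KD 1, 33 without KAT2B_KD 2 and 27 without NT 2, and the interferon genes numbered 12, 17 and 18.

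Late differentiation genes stood below NT in differentiated KAT2B_KD cultures, where 501 genes were lower and 263 higher. Of the 22 granular genes 13 fell and 0 rose, of 25 SPRR and LCE genes 16 fell and 0 rose, and of 23 lipid barrier genes 12 fell and 0 rose. LCE3D fell by 4.60 log2 (SE 0.30, adjusted p = 1.49e-07), from 105 ± 19.8 to 4.33 ± 0.432 CPM, and LOR, which encodes loricrin, from 79.5 ± 2.09 to 3.37 CPM (-4.56, SE 0.45, adjusted p = 0.000166). The filaggrin-processing protease ASPRV1 (-3.77, SE 0.35), the desquamation protease KLK7 (-2.84, SE 0.28, adjusted p = 9.60e-06) and the sphingomyelinase SMPD3 (-3.70, SE 0.55) also fell. The early keratins KRT1 (-0.37 log2, adjusted p = 0.545) and KRT10 (-0.28, adjusted p = 0.740) did not pass. Of the 20 spinous genes 7 fell and 0 rose (list median -0.68), a count that moved with 1 library left out, as given below.

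Some proliferation genes and, among the basal genes, the regulator TP63 were higher in these cultures. Of 28 mitosis genes 11 rose, with TPX2 3.05-fold higher (log2 1.61, SE 0.26, adjusted p = 0.000994, 10.3 ± 0.445 CPM against 3.34 ± 0.854), and of 28 replication genes 7 rose, including RRM2 (log2 1.66, SE 0.24). TP63 was 2.19-fold higher (log2 1.13, SE 0.18, adjusted p = 0.000976). It was the only 1 of 20 basal genes that rose, while 1 fell, and the basal list (median -0.085) did not pass. The amino acid stress genes MTHFD2 (-1.47, SE 0.19, adjusted p = 0.000201) and TRIB3 (-1.34) fell.

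Medians that passed with both correlations were -1.59 for granular (adjusted p = 0.00122 with an estimated correlation, 17 lower adjusted over the list alone), -2.52 for SPRR and LCE (0.0183, 22), -1.17 for lipid barrier (0.00122, 17) and 1.44 for mitosis genes (0.0230, 20 higher). The estimated correlation ended the calls of spinous (adjusted p = 0.0842, median -0.68, 7 fell), replication (0.0886, 0.72), amino acid stress (0.0886, -0.70, 4 fell, 12 adjusted over the list alone), transcription factors (0.238), MYC targets (0.274), interferon (0.612, -0.35, 4 fell) and cholesterol genes (0.425). The 764 changed genes became 370 without KAT2B_KD 1, 370 without NT 1 and 281 without NT 2. Without KAT2B_KD 1, KAT2B_KD 2, NT 1 and NT 2 the SPRR and LCE genes that passed were 8, 6, 9 and 7, the spinous genes 5, 3, 4 and 4, the lipid barrier genes 8, 9, 8 and 7, the mitosis genes 9, 4, 10 and 1, the replication genes 5, 3, 6 and 1, the amino acid stress genes 5, 2, 2 and 2 and the interferon genes 2 in each fit.

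Before differentiation, KAT2AB_KD cells had higher spinous and granular lists than NT cells. At Subconfluent NOTCH3 was 17.9-fold higher (log2 4.16, SE 0.41, adjusted p = 9.52e-06, 21.5 ± 2.70 CPM against 1.20) and TGM1 11.8-fold (log2 3.57, SE 0.37, adjusted p = 1.38e-05). LCE3D, LCE3E and ASPRV1, at 0 reads in NT, were at least 17.3-fold, 15.8-fold and 15.5-fold higher. Of 20 spinous genes 5 rose, of 22 granular genes 5, of 25 SPRR and LCE genes 10 and of 23 lipid barrier genes 3. VIM fell by 3.31 log2 (SE 0.32, adjusted p = 9.52e-06), from 134 ± 38.0 to 13.5 ± 0.101 CPM, while the mesenchymal list members MMP10 (2.60, SE 0.25), MMP1 (2.03) and the actin-binding gene TAGLN (2.19) rose.

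Medians at Subconfluent were 1.24 for spinous (adjusted p = 0.0205 with an estimated correlation, 11 adjusted over the list alone), 1.62 for granular (0.0276, 9, 0.79 at the bound) and 1.34 for lipid barrier (0.0457, but adjusted p = 0.0525 with RLE scaling, 8, 0.53 at the bound). Calls lost with an estimated correlation were SPRR and LCE (adjusted p = 0.0759, median 1.92, or 1.55 at the bound, 13 adjusted over the list alone), transcription factors (0.0759, 3 rose), amino acid stress (0.0727, 0.82, or 0.73 at the bound, 4 rose, 13 adjusted over the list alone), barrier stress (0.252, 5 rose), interferon (0.269, -0.51), p53 (0.153) and MYC targets (0.467). A total of 293 genes were higher and 132 lower, 425 in all, and 155 without KAT2AB_KD 1, 157 without KAT2AB_KD 2, 152 without NT 1 and 150 without NT 2. In the same order 3, 3, 3 and 3 spinous, 4, 3, 4 and 3 granular, 6, 10, 9 and 5 SPRR and LCE, 2, 2, 1 and 1 lipid barrier, 3, 2, 0 and 2 transcription factor, 2, 1, 0 and 0 amino acid stress and 4, 3, 2 and 2 barrier stress genes rose.

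At Confluent the same lists stood above NT and interferon genes below. MMP10 was 18.8-fold higher (log2 4.24, SE 0.27, adjusted p = 3.68e-08, 40.1 ± 3.04 CPM against 2.11 ± 0.435), and the spinous genes NOTCH3 (2.18, adjusted p = 0.000596) and SBSN rose, the latter with a ratio of 61.9 (95% interval 16.9 to 515.7) over 2 reads in NT. Of 20 spinous genes 9 rose, of 22 granular genes 7, of 25 SPRR and LCE genes 10 and of 21 transcription factors 5, and of 32 interferon genes 26 fell. MX2 fell by 3.84 log2 (SE 0.47, adjusted p = 7.23e-05) and VIM went from 75.7 ± 0.328 to 9.04 ± 0.368 CPM (-3.07, adjusted p = 1.83e-05).

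The Confluent medians were 1.19 for spinous (adjusted p = 0.00862 with an estimated correlation, 10 adjusted over the list alone), 1.96 for granular (0.00909, 9, 1.74 at the bound), 2.14 for SPRR and LCE (0.0247, 14, 2.04 at the bound), 1.09 for lipid barrier (0.0247, 3 rose, 4 over the list alone, 0.47 at the bound), 0.35 for transcription factors (0.0247) and -1.91 for interferon genes (0.00862, 32). The estimated correlation ended the calls of other acetyltransferases (adjusted p = 0.430), MYC targets (0.410), cholesterol genes (0.410) and fibroblast markers (0.196). Of 359 changed genes 219 were higher and 140 lower, with 164 in all without KAT2AB_KD 1, 150 without NT 1 and 188 without NT 2. Without KAT2AB_KD 1, KAT2AB_KD 2, NT 1 and NT 2 the spinous genes were 6, 8, 5 and 2, the granular genes 2, 6, 0 and 3, the SPRR and LCE genes 9, 9, 5 and 3, the lipid barrier genes 1, 4, 1 and 0, the transcription factors 3, 4, 2 and 4 and the interferon genes 12, 17, 20 and 17.

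In differentiated KAT2AB_KD cultures LCE3D rose above NT, whereas it fell in KAT2B_KD. It stood at 462 ± 46.6 CPM against 105 ± 19.8 (log2 2.13, SE 0.26, adjusted p = 0.000276) and LCE3C was 2.17 log2 higher (adjusted p = 0.00105). MMP10 was 10.6-fold higher (log2 3.41, SE 0.25, adjusted p = 4.58e-07) and MMP1 3.29 log2 higher (SE 0.26). The spinous keratin KRT1 fell by 1.87 log2 (SE 0.29, adjusted p = 0.00169), and the growth factor-like gene IGFL1 was also lower (-4.14, SE 0.36). Of 24 amino acid stress genes 6 fell (0 without NT 2, and the list call was lost at adjusted p = 0.0929 with an estimated correlation), among them ATF4 (-1.10, adjusted p = 0.0144, lost without KAT2AB_KD 1 at 0.0573, KAT2AB_KD 2 at 0.0768 or NT 2 at 0.152) and STC2 (-2.97, lost without KAT2AB_KD 1 at 0.0812 or NT 2 at 0.0655).

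Every list call at this stage was lost with an estimated correlation. For SPRR and LCE (4 rose, 17 adjusted over the list alone, median 1.34) the preset correlation gave 3.20e-11 and the estimated one adjusted p = 0.212, and for amino acid stress (13 lower adjusted over the list alone, median -0.86) 3.32e-11 and 0.0929. The others were cholesterol (adjusted p = 0.273 with an estimated correlation, 5 rose, 9 adjusted over the list alone), mesenchymal (0.373, 6 rose, 1 fell), barrier stress (0.451), hypoxia (0.451), interferon (0.668) and mitosis genes (0.614). There were 247 genes higher and 184 lower, 431 together, but 112 without KAT2AB_KD 1, 138 without NT 1 and 67 without NT 2. Amino acid stress genes then numbered 1, 3 and 0, cholesterol genes 1, 1 and 2, and mesenchymal genes that rose 4, 5 and 2.

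**Figure D2:**
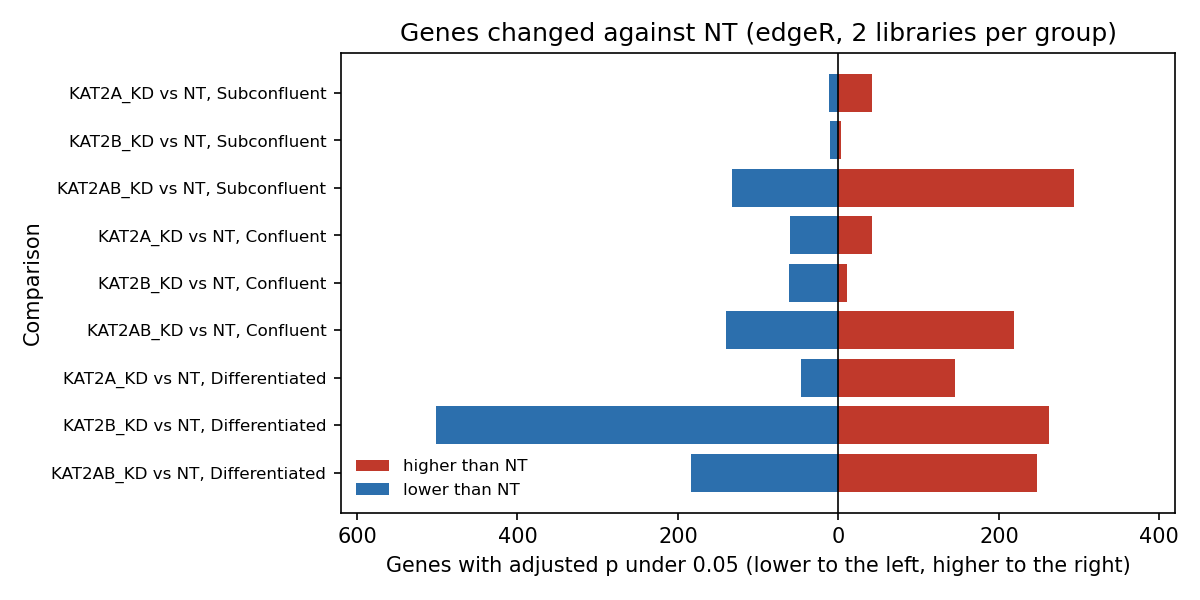
Genes that passed (horizontal axis, number of genes) above NT to the right and below NT to the left, for each knockdown and stage (vertical axis), edgeR with 2 libraries per group. Bars reach 293 higher and 132 lower for KAT2AB_KD at Subconfluent and 263 higher and 501 lower for KAT2B_KD at Differentiated.

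**Figure D3:**
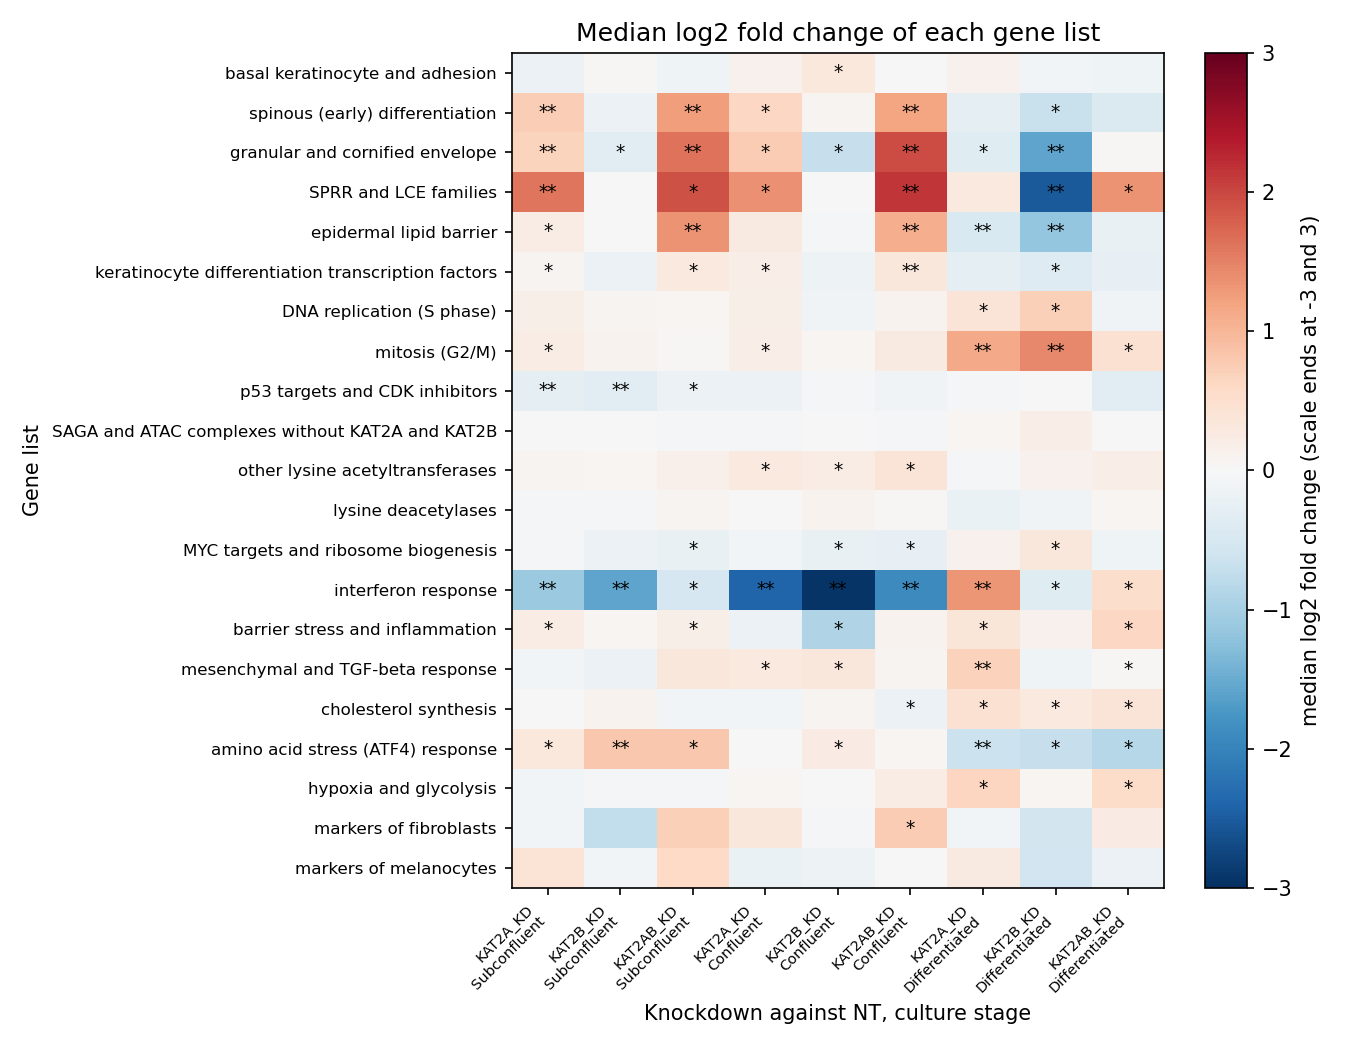
Median log2 fold change (colour, scale ends at -3 and 3) of each gene list (vertical axis) in each knockdown against NT by stage (horizontal axis). A single star marks an adjusted p under 0.05 with the preset correlation and a double star one that also passed with an estimated correlation, as for interferon genes in KAT2B_KD at Confluent with a median of -2.93.

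No list shift of SAGA and ATAC subunits, deacetylases or melanocyte markers passed in any knockdown against NT, with lowest adjusted p of 0.254, 0.0640 and 0.144.

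The series title asks how the paralogs diverge, which the direct contrast of KAT2A_KD and KAT2B_KD addresses without the NT libraries. At Subconfluent the spinous, granular, SPRR and LCE and transcription factor lists were higher in KAT2A_KD than in KAT2B_KD. There KRTDAP, a differentiation-associated secreted protein gene, was 5.27 log2 higher (SE 0.71, adjusted p = 0.000613), NOTCH3 4.35 higher (SE 0.50), PI3 4.89 (SE 0.65) and SPRR1B 11.9-fold higher (log2 3.58, SE 0.41, adjusted p = 0.000116), and VIM was at 39.9 ± 6.61 CPM against 284 ± 9.33 (log2 -2.83, SE 0.31, adjusted p = 9.10e-05). Of the spinous genes 3 were higher, of the granular 2, of SPRR and LCE 6 and of lipid barrier 1, with 7, 8, 11 and 5 adjusted over the list alone. Their medians were 0.84 (adjusted p = 0.00262 with an estimated correlation), 1.10 (0.00262), 2.06 (0.0175, 1.98 at the bound) and 0.42 (0.0472, but adjusted p = 0.0517 with RLE scaling, 0.050 at the bound), and that of the transcription factors 0.17 (0.0193). Calls lost with an estimated correlation were interferon (adjusted p = 0.234), barrier stress (0.181, 4 higher), mesenchymal (0.170), amino acid stress (0.0600, median -0.38) and fibroblast markers (0.124). There were 75 genes higher and 9 lower, 84 in all, and 34 without KAT2A_KD 1, 45 without KAT2A_KD 2, 31 without KAT2B_KD 1 and 33 without KAT2B_KD 2. In that order SPRR and LCE genes were 3, 4, 3 and 5, granular genes 1, 1, 1 and 2, barrier stress genes 3, 2, 2 and 1, and lipid barrier genes 0.

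At Confluent MMP10 was higher in KAT2A_KD than in KAT2B_KD (log2 2.36, SE 0.26, adjusted p = 0.000288) and VIM lower (-2.45, adjusted p = 0.00111). The granular list median was 1.65 (adjusted p = 0.0318 with an estimated correlation, 7 higher adjusted over the list alone, 0.54 at the bound). The estimated correlation ended the calls of spinous (adjusted p = 0.0534, 2 higher), SPRR and LCE (0.0534, median 1.52, or 1.44 at the bound, 5 higher, 11 over the list alone), transcription factors (0.0932), barrier stress (0.153) and cholesterol genes (0.460). Of 45 genes 40 were higher and 5 lower, and 2 passed without KAT2B_KD 1, 24 without KAT2B_KD 2 and 24 without KAT2A_KD 2. In these fits SPRR and LCE genes numbered 0, 3 and 3 and spinous genes 0, 1 and 1, with 1 and 0 without KAT2A_KD 1.

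In differentiated cells 21 of 25 SPRR and LCE genes, 10 of 22 granular genes and 17 of 32 interferon genes were higher in KAT2A_KD than in KAT2B_KD, and 0 of these lists lower. LCE3D was 18.2-fold higher (log2 4.18, SE 0.30, adjusted p = 5.53e-07), LOR 4.18 log2 (SE 0.44, adjusted p = 0.000277), KLK7 1.99 (SE 0.27), the interferon gene IFI44 3.88 (SE 0.43, adjusted p = 2.91e-05) and MMP1 2.63 (adjusted p = 8.14e-06). Medians were 2.85 for SPRR and LCE (adjusted p = 0.00563 with an estimated correlation, 22 adjusted over the list alone), 1.60 for granular (0.00563, 15), 0.58 for lipid barrier (0.0147, 4 higher, 1 lower, 9 and 1 over the list alone), 2.07 for interferon (0.0121, 30) and 0.92 for mesenchymal genes (0.00563, 8 higher, 12). Calls lost with an estimated correlation were spinous (adjusted p = 0.291, 4 higher), mitosis (0.526), MYC targets (0.291), hypoxia (0.291) and barrier stress (0.349). In all 319 genes were higher and 56 lower, 375 together, but 147 without KAT2B_KD 1 and 97 without KAT2A_KD 1. Without KAT2A_KD 1, KAT2A_KD 2, KAT2B_KD 1 and KAT2B_KD 2, spinous genes were 2, 4, 3 and 2, SPRR and LCE genes 5, 20, 12 and 6, granular genes 4, 9, 5 and 8, lipid barrier genes 0, 4, 1 and 2, interferon genes 10, 13, 14 and 10 and mesenchymal genes 4, 7, 6 and 6.

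Few genes passed between KAT2AB_KD and KAT2A_KD before differentiation. At Subconfluent edgeR called 0 genes between them, with 10 by DESeq2 and 90 with no filter on low counts. There KAT2A was at 8.29 and 10.4 CPM in KAT2AB_KD and at 3.46 and 4.12 in KAT2A_KD. The contrast therefore does not isolate the knockdown of KAT2B. At an unadjusted p under 0.05 there were 819, close to the number that 15757 tests give with no change. At Subconfluent the preset correlation gave calls for spinous (median 0.31), granular (0.50, or 0.31 at the bound), lipid barrier (0.36, or 0.29 at the bound), interferon (0.44) and amino acid stress genes (0.43), each lost at adjusted p = 0.333 with an estimated correlation, and for mitosis genes (-0.19, 0.597). At Confluent edgeR called 1 gene, the serine protease gene TMPRSS13 (log2 3.52, SE 0.448, adjusted p = 0.00282), a call lost without KAT2A_KD 2 (adjusted p = 0.265). There were 2 without KAT2AB_KD 2, 23 without KAT2A_KD 1 and 0 by the same edgeR test without KAT2A_KD 2. With all libraries 491 genes had an unadjusted p under 0.05, fewer than 15757 tests give on average with no change, and DESeq2 called 14. The spinous and granular lists had medians of 0.61 and 0.57 at Confluent (adjusted p = 0.0475 for each with an estimated correlation), with 0 members past the threshold. Lost there with an estimated correlation were the calls of SPRR and LCE (adjusted p = 0.284), lipid barrier (0.0567), transcription factor (0.177), interferon (0.309) and basal (0.549) genes, of which the SPRR and LCE and interferon medians were 0.78 and 0.39. At Differentiated 20 genes were higher and 30 lower, 50 in all (with DESeq2 53.6% of 181 were higher). LCE3C was higher at 163.8 ± 26.6 CPM against 28.2 ± 4.34 (log2 2.54, SE 0.33, adjusted p = 0.00118). The count was 6 without KAT2AB_KD 1, 12 without KAT2A_KD 1 and 12 without KAT2A_KD 2. Of SPRR and LCE genes 4 were higher (median 1.11, adjusted p = 0.119 with an estimated correlation), and of interferon genes 5 were lower (-1.002, 0.119), in number 0 without KAT2AB_KD 1, 10 without KAT2AB_KD 2, 0 without KAT2A_KD 1 and 3 without KAT2A_KD 2. Mitosis (-0.78, 0.239) and replication genes (-0.58, 0.119) had 9 and 7 members lower adjusted over the list alone. The calls of basal (adjusted p = 0.349), granular (0.295) and lipid barrier (0.266) genes were also lost with an estimated correlation.

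Against KAT2B_KD the granular list of the double knockdown was higher at every stage, with medians and tests in the next paragraph. At Subconfluent NOTCH3 was 5.78 log2 higher (SE 0.478, adjusted p = 8.53e-07) and PI3 5.87 (SE 0.662), and at Confluent PI3 was 5.16 higher (SE 0.603) and VIM lower (-4.14, SE 0.331). At Differentiated LCE3D was 106-fold higher (log2 6.73, SE 0.33, adjusted p = 9.87e-10), SMPD3 4.73 log2 and IVL 1.69, while TP63 fell by 1.19 (SE 0.18, adjusted p = 0.000242) and RRM2 by 1.92 (SE 0.25). Of 25 SPRR and LCE genes 22 were higher, of 22 granular genes 13 and of 23 lipid barrier genes 11 (1 lower), and 12 of 28 replication and 11 of 28 mitosis genes were lower.

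The medians at Differentiated were 3.95 (adjusted p = 0.0142 with an estimated correlation), 1.83 (0.0132), 0.78 (0.0174), -0.94 (0.132, a call lost) and -1.22 (0.162, a call lost), while the spinous (0.019, 0.525) and transcription factor lists (0.21, 0.547) did not pass with either correlation. At Subconfluent spinous (1.23, 0.00729), granular (2.03, or 1.18 at the bound, 0.00729), lipid barrier (1.74, or 0.75 at the bound, 0.0170) and transcription factor lists (0.0354) passed with both correlations, with 6, 7, 4 and 5 genes higher, and the SPRR and LCE call was lost (0.0699, 9 higher). At Confluent spinous (0.98, 0.00630), granular (2.68, or 1.48 at the bound, 0.00349), SPRR and LCE (2.85, or 2.39 at the bound, 0.0263) and transcription factor lists (0.0263) passed, with 8, 8, 11 and 4 genes higher. Other list calls lost with an estimated correlation were, at Subconfluent, interferon (adjusted p = 0.109), barrier stress (0.226), mesenchymal (0.1896), cholesterol (0.395) and fibroblast (0.0735) genes. At Confluent they were basal (adjusted p = 0.206), lipid barrier (0.0596), interferon (0.206), barrier stress (0.167) and cholesterol (0.167) genes, and at Differentiated MYC target (adjusted p = 0.244), interferon (0.463), barrier stress (0.513) and mesenchymal (0.162) genes. The number of changed genes was 411 at Subconfluent (178 without KAT2AB_KD 1, 189 without KAT2AB_KD 2, 144 without KAT2B_KD 1, 270 without KAT2B_KD 2). At Confluent it was 254 (129 without KAT2AB_KD 1, 78 without KAT2B_KD 1, 120 without KAT2B_KD 2), and at Differentiated 1739 (1018 without KAT2AB_KD 2, 682 without KAT2B_KD 1). Among the Differentiated lists the lipid barrier count was 6 without KAT2AB_KD 2, the replication count 7 without KAT2AB_KD 1 and 6 without KAT2B_KD 2, and the mitosis count 6 without KAT2AB_KD 1 or KAT2B_KD 2. At Subconfluent the granular count was 3 without KAT2B_KD 1, the SPRR and LCE count 5 without KAT2B_KD 2 and the transcription factor count 3 without either. At Confluent without KAT2B_KD 1 there were 2 spinous, 2 granular, 5 SPRR and LCE and 1 transcription factor genes, without KAT2B_KD 2 there were 5 spinous and 4 granular genes, and without KAT2AB_KD 1 there were 4 granular genes.

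The change from Subconfluent to Differentiated itself differed from that of NT in each knockdown. In KAT2A_KD the difference was above 0 for 17 of 32 interferon genes, such as IFIT3 (log2 difference 4.92, SE 0.50, adjusted p = 7.52e-05) and IFIT1 (4.89, SE 0.56), and below 0 for NOTCH3 (-3.39, adjusted p = 0.00364) and TGM1 (-2.85, adjusted p = 0.00578). In KAT2B_KD it was below 0 for 6 of 24 amino acid stress genes, led by the mitochondrial folate enzyme gene MTHFD2 (-2.33, SE 0.27, adjusted p = 0.000786). In KAT2AB_KD the difference was -4.54 for NOTCH3 (SE 0.51, adjusted p = 0.000108), -4.30 for TGM1 (SE 0.47), -5.82 for STC2 (SE 0.83) and -1.91 for ATF4 (SE 0.32, adjusted p = 0.00356), and 8 of 24 amino acid stress genes were lower.

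The list differences that passed with both correlations in KAT2A_KD included interferon (median 2.57, adjusted p = 0.0102 with an estimated correlation, 27 adjusted over the list alone) and spinous genes (-0.95, 0.0102, 2 lower). In KAT2B_KD they included amino acid stress (-1.57, 0.00604, 14 lower over the list alone, -1.28 at the bound), SPRR and LCE (-1.88, 0.0223, -2.06 at the bound, 2 higher and 4 lower over the list alone) and mitosis genes (1.38, 0.0449, 2 higher). In KAT2AB_KD they included amino acid stress (-1.80, 0.0113, 19 over the list alone), spinous (-1.26, 0.0113, 6 lower) and granular genes (-1.84, 0.0341, 5 lower, -1.43 at the bound). The granular list of KAT2AB_KD stood above NT at Subconfluent (median 1.62) and did not pass at Differentiated (0.044). Calls lost with an estimated correlation were, in KAT2A_KD, SPRR and LCE (adjusted p = 0.128), transcription factor (0.128), replication (0.423), mitosis (0.128), cholesterol (0.139) and hypoxia (0.139) genes. In KAT2B_KD they were spinous (adjusted p = 0.201), replication (0.154), MYC target (0.154) and interferon (0.154) genes, and in KAT2AB_KD transcription factor (adjusted p = 0.131), interferon (0.368), cholesterol (0.131) and hypoxia (0.666) genes.

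The differences in stage change covered 73 genes in KAT2A_KD, 52 in KAT2B_KD and 315 in KAT2AB_KD. For KAT2A_KD the number was 30 without KAT2A_KD Subconfluent 1, 32 without KAT2A_KD Subconfluent 2, 46 without KAT2A_KD Differentiated 1, 31 without NT Subconfluent 1 and 20 without NT Differentiated 2. For KAT2B_KD it was 23 without KAT2B_KD Subconfluent 1, 9 without KAT2B_KD Subconfluent 2, 30 without KAT2B_KD Differentiated 2, 6 without NT Subconfluent 1, 15 without NT Subconfluent 2 and 11 without NT Differentiated 2. For KAT2AB_KD it was 95 and 88 without KAT2AB_KD Subconfluent 1 and 2, 157 without KAT2AB_KD Differentiated 1, 98 and 118 without NT Subconfluent 1 and 2, and 160 and 127 without NT Differentiated 1 and 2. The 17 interferon genes of KAT2A_KD were 8 without KAT2A_KD Subconfluent 1 and 4 without NT Differentiated 2, and 10 without KAT2A_KD Subconfluent 2, KAT2A_KD Differentiated 1 or NT Subconfluent 1. The 6 amino acid stress genes of KAT2B_KD were 1 without KAT2B_KD Subconfluent 2, NT Subconfluent 1 or NT Differentiated 2, 3 without NT Subconfluent 2 and 4 without KAT2B_KD Differentiated 2, and the 8 of KAT2AB_KD were 3 without KAT2AB_KD Subconfluent 1 or 2, NT Subconfluent 1 or 2 or NT Differentiated 2, 4 without KAT2AB_KD Differentiated 1 and 5 without NT Differentiated 1. The 2 mitosis genes of KAT2B_KD were 3 without NT Differentiated 1 and 0 in each other fit. In KAT2AB_KD the 6 spinous genes were 3 without KAT2AB_KD Subconfluent 1 or NT Subconfluent 1, and the 5 granular genes were 1 without KAT2AB_KD Subconfluent 1 or 2, NT Subconfluent 1 or 2 or NT Differentiated 1 and 2 without KAT2AB_KD Differentiated 1 or NT Differentiated 2.

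KAT2A_KD and KAT2B_KD moved some genes in the same direction against NT. They shared 5 genes at Subconfluent (1 higher, 4 lower), 42 at Confluent (6 higher, 36 lower) and 84 at Differentiated (59 higher, 25 lower), with 0, 0 and 2 in opposite directions. At Confluent, with all libraries, 24 and 28 of the same 32 interferon genes fell in KAT2A_KD and KAT2B_KD. Interferon genes are thus most of the 36, and for them a difference in the NT cultures remains open. Independent lists with as many genes as passed in each knockdown would share 0.0080 genes higher and 0.00838 lower at Subconfluent. For Confluent these were 0.0293 and 0.236, and for Differentiated 2.42 and 1.49. The 20 simulations of unchanged groups, with NT libraries simulated too and genes drawn independently, shared 0 at most. They cannot show overlap that arises when many genes depart together in the real NT libraries. Without KAT2A_KD 1, KAT2A_KD 2, KAT2B_KD 1, KAT2B_KD 2, NT 1 and NT 2 the genes shared in the same direction were 1, 1, 2, 0, 0 and 2 at Subconfluent and 24, 17, 17, 22, 24 and 18 at Confluent. At Differentiated they were 25 without KAT2A_KD 1, 37 without KAT2A_KD 2, 53 without KAT2B_KD 2, 37 without NT 1 and 3 without NT 2, and the 2 opposite genes were 0 without KAT2A_KD 1, NT 1 or NT 2 and 1 without KAT2A_KD 2 or KAT2B_KD 2. The correlation of fold changes across genes was 0.473, 0.468 and 0.498, against 0.514, 0.481 and 0.505 in the simulations. The covariance was 0.253, 0.302 and 0.365 against 0.157, 0.154 and 0.162, a difference of 0.0968, 0.148 and 0.204. For KAT2AB_KD the covariance differences were 0.328, 0.314 and 0.237 with KAT2A_KD and 0.0623, 0.142 and 0.0561 with KAT2B_KD. Since NT has 2 libraries per stage these cannot be split, and part of the excess may come from the shared controls.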

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

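The tests of the differences below were set before the data were examined. Of the tests that weigh the 3 patterns, those of NT libraries that stand apart, of KAT2A at every stage, of a share of undifferentiated cells and of shared reads were chosen only after the result was seen.

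The change from Subconfluent to Differentiated differed from that of NT, by a test of the difference itself, for 73 genes in KAT2A_KD, 52 in KAT2B_KD and 315 in KAT2AB_KD. The same test (camera with an estimated correlation) passed for these lists. In KAT2A_KD the median log2 differences were -0.951 for spinous, -1.23 for granular, -0.730 for lipid barrier, 2.57 for interferon, 0.571 for mesenchymal and TGF-beta and -1.06 for amino acid stress genes. In KAT2B_KD they were -1.63 for granular, -1.88 for SPRR and LCE, -1.16 for lipid barrier, 1.38 for mitosis and -1.57 for amino acid stress genes. In KAT2AB_KD they were -1.26 for spinous, -1.84 for granular, -1.36 for lipid barrier and -1.80 for amino acid stress genes. With members at 0 reads at their bound, the lipid barrier median of KAT2A_KD was -0.669. In KAT2B_KD the granular, SPRR and LCE, lipid barrier and amino acid stress medians were then -1.40, -2.06, -0.794 and -1.28, and in KAT2AB_KD the granular, lipid barrier and amino acid stress medians -1.43, -0.667 and -1.64. A difference below 0 can come from a higher start or a lower end. Against NT, the granular median of KAT2AB_KD was 1.62 at Subconfluent (0.79 at the bound) and 0.044 at Differentiated, where the list did not pass. That of KAT2B_KD was -0.33 and -1.59 at these stages.

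Interferon genes were lower in every knockdown than in NT at Confluent. NT libraries of this stage that stand apart may account for it, since their list levels of 5.39 and 5.74 were above the other 22 (4.75 at most), while the smallest adjusted p between knockdowns was 0.206 (camera with an estimated correlation), which does not show that the knockdowns are equal, and the preset correlation called KAT2AB_KD above KAT2A_KD (median 0.39, adjusted p = 1.34e-06) and KAT2B_KD (0.595, 1.80e-07). Against this as the only source of lower interferon genes, the list was also lower at Subconfluent, against other NT libraries, in KAT2A_KD (median -1.10, adjusted p = 0.0216) and KAT2B_KD (-1.59, 0.00544), though not past the threshold in KAT2AB_KD (-0.51, 0.269). A single NT library does not account for the pattern, as at least 16 members were lower in each knockdown without either NT library, and a fall in KAT2A_KD at every stage is excluded by its median of 1.32 at Differentiated. An effect of each knockdown and a difference in the NT cultures both remain open at Confluent, because all knockdowns are compared there with the same 2 libraries.

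Granular and cornified envelope genes were lower in KAT2B_KD than in NT at Differentiated (median -1.59). Dividing undifferentiated cells account for little of it by the mitosis list. The share estimated from it, 3.86% (10.8% at most), would give -0.0568 (-0.165). Of the 22 granular members 22 lay below the first value (exact Wilcoxon signed rank test across members, which are not independent replicates, p = 4.77e-07). The fall of this list is what prompted the test, so this p adds no support. Cells that neither divide nor differentiate would need a share of 66.7%, which would give -1.42 in genes induced at least 16-fold in NT; of 624 such genes outside the list 154 (24.7%) lay above this by more than 2 SE, among them KRT1 (-0.37) and KRT10 (-0.28), and 63 lay below. The 24.7% is above the small share that the test allowed if such cells were the only source. It is also short of the majority that the test required to count against such cells, so the test cannot decide. The median of the induced genes was -1.15 (quartiles -1.96 and -0.476). A share of such cells cannot be told apart from lower expression in each cell while no value counts them. A single library does not account for the pattern, with at least 9 members lower when any library was left out. Reads shared within the SPRR and LCE families do not either, with 13 granular genes lower that belong to neither family. Of the granular list 0 genes were flagged as sharing reads, but the flag sees only equal counts or whole multiples in all libraries. Partial sharing was not tested.

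Differentiation genes were higher in KAT2A_KD than in NT at Subconfluent. Denser KAT2A_KD cultures may account for this, since 139 genes outside the lists that rose with confluence in KAT2B_KD stood 0.503 log2 above 72 that fell (medians 0.358 and -0.145). The interferon list rose with confluence in NT (median 1.90) and was lower in KAT2A_KD (-1.10). The NT Confluent libraries may stand apart, but the list level also rose with confluence in each knockdown. In KAT2A_KD it went from 2.28 and 2.38 to 2.91 and 2.80, and in KAT2B_KD from 1.88 and 1.74 to 2.51 and 2.77. Denser cultures alone would therefore not give a lower list. The interferon values cannot decide whether density adds to another difference from NT. The list was also lower at Subconfluent in KAT2B_KD (-1.59), where no differentiation list passed upward. The risen and fallen genes used here may themselves belong to differentiation. A single library does not account for the sign of the pattern. The SPRR and LCE median was 1.66 to 1.70 without NT 2 or either KAT2A_KD library and 3.95 without NT 1. These medians are fitted, and members at 0 reads in a group, 6 with all libraries, were not set to their bound. The calls of single spinous and SPRR and LCE genes did not hold when either NT library was left out.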

How the results depend on the processing

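The fit without genes that share reads was chosen only after the data were seen; the other tests were set before. No call of a named gene or list reversed in the alternative fits. The balance of higher and lower calls did turn in some comparisons. With DESeq2 the share higher went from 41.2% to 52.9% for KAT2A_KD against NT at Confluent. It went from 40% to 53.6% for KAT2AB_KD against KAT2A_KD at Differentiated. With RLE it went from 48.2% to 50.9% in NT from Confluent to Differentiated. From Subconfluent to Differentiated it went from 47.5% to 50.9%. RLE scaling and the fit without shared reads kept all 30 counts of genes within 1.5 times, DESeq2 kept 5 and the fit with no filter 4. Of 858 calls of named genes, 851 passed with DESeq2, 855 with RLE, 850 with no filter and 857 with the replicate block. Leaving out 1 library kept 2563 of 3772. Of 217 calls of lists, 88 passed with an estimated correlation and 216 with RLE or with the block. With RLE, 86 of the 88 also passed, and the lipid barrier calls of KAT2AB_KD against NT (adjusted p = 0.0525) and of KAT2A_KD against KAT2B_KD (0.0517) at Subconfluent were lost. With members at 0 reads at their bound, 46 list medians moved by over 0.05 log2 and 1 changed sign. In the simulation, with 2 libraries per group at the depth of the data (8010178 counts in the smallest library), 26% of genes changed 2-fold and 75% of those changed 4-fold were recovered. For the counts that follow, the cause was not tested.

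With no filter and with DESeq2, changed genes were 430 and 377 in NT from Subconfluent to Confluent (142 reported). Against NT they were 223 and 133 for KAT2A_KD, 104 and 66 for KAT2B_KD and 762 and 721 for KAT2AB_KD at Subconfluent. At Confluent they were 302 and 187, 212 and 154, and 747 and 601, and at Differentiated 506 and 497 for KAT2A_KD and 782 and 735 for KAT2AB_KD. KAT2A_KD against KAT2B_KD gave 210 and 130, 204 and 100, and 675 and 628 over the 3 stages. KAT2AB_KD against KAT2A_KD gave 90 and 10, 92 and 14, and 240 and 181, and against KAT2B_KD 684 and 693 at Subconfluent and 520 and 397 at Confluent. Differences in stage change were 271 and 210 for KAT2A_KD, 284 and 264 for KAT2B_KD and 634 and 666 for KAT2AB_KD. Genes shared by the single knockdowns were 36 and 23, 97 and 77, and 214 and 209 in the same direction over the stages. In opposite directions they were 11 and 4 at Subconfluent, 8 and 2 at Confluent and, with no filter, 10 at Differentiated.

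Leaving out 1 library gave 40 to 91 genes in NT from Subconfluent to Confluent. Against NT the ranges at Subconfluent were 11 to 18 for KAT2A_KD, 0 to 8 for KAT2B_KD and 150 to 157 for KAT2AB_KD. At Confluent they were 35 to 57, 20 to 51 and 150 to 289, and at Differentiated 17 to 99, 281 to 534 and 67 to 326. KAT2A_KD against KAT2B_KD ranged from 31 to 45, 2 to 35 and 97 to 292. KAT2AB_KD against KAT2A_KD ranged from 0 to 23 at Confluent and 6 to 56 at Differentiated, and against KAT2B_KD from 144 to 270, 78 to 195 and 682 to 1956. Differences in stage change ranged from 20 to 75, 6 to 38 and 88 to 427. Shared genes ranged from 0 to 2, 17 to 24 and 3 to 66 in the same direction and from 0 to 2 in opposite directions at Differentiated.

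By the rule set for this, the replicate numbers were not taken to pair the libraries. Of 66 correlations between groups, in the difference between the replicates, 37 were over 0.1 (-0.26 to 0.41, median 0.12). A weak effect shared by replicate number is not excluded. With the number as a block, counts rose in most comparisons, as from 142 to 172 in NT from Subconfluent to Confluent. For KAT2B_KD against NT at Differentiated the count rose from 764 to 870. With the number as a block, KAT2AB_KD against KAT2A_KD at Confluent had 3 genes and the difference in stage change of KAT2B_KD 91, and the other 28 counts stayed within 1.5 times. Of the 88 list calls with an estimated correlation, 81 passed with the block, and the lost ones are not marked where they are reported.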

Other observations

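No test in this part was chosen after a result was seen. FAM50A, which encodes a nuclear protein linked to splicing, was lower in KAT2AB_KD than in NT at each stage. It stood at 0.774 ± 0.0309 CPM (SD, n = 2) against 8.72 ± 0.180 at Subconfluent (log2 -3.48, SE 0.54, adjusted p = 0.000788), at 0.535 ± 0.365 against 5.64 ± 2.13 at Confluent (adjusted p = 0.00155) and at 1.29 ± 0.968 against 11.5 ± 4.86 at Differentiated (adjusted p = 0.00243). Between KAT2AB_KD and KAT2A_KD, FAM50A did not pass at Subconfluent or Confluent. The lower level is thus not shown to be particular to the double knockdown.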
